A study of Mus musculus with 29 samples.

How the data were processed

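RNA-seq was analysed for 29 mouse libraries in 6 groups, 5 libraries each for Control, Obese, LFD, LFCR and ICR and 4 for MCR, grouped by the treatment field of the labels. Per the labels' protocols, total RNA was extracted with TRIzol from the mammary fat pad opposite the tumor-bearing side, libraries were made with a stranded total RNA kit, and paired reads of 76 bases were sequenced on a HiSeq 2000 instrument. Per the submitters' processing notes, TopHat2 2.0.7, HTSeq 0.5.3p9 and DESeq2 were used with the mm10 build. The version of the last tool, the annotation and the counting options are not given in the sources used here.

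The deposited table holds 30818 gene symbols with 1 value per library on a log2 scale, made by the authors. All 29 columns share 1 lowest value, 3.75, and reach 22.0 at most. Undoing the closed form of a variance-stabilising transform with that lowest value as 0 reads gave whole multiples of 1 step in every library. Within a tolerance of 0.01, 100% of the values were whole reads in each library, and the largest distance from a whole number was 9.87e-08. The values are therefore taken as variance-stabilised log2 values of size-factor-normalized counts. That inference comes from the values, since no source used here states the transform. The transform compresses low values, so every log2 difference printed here understates the change of low genes, and counts are given beside log2 differences where the level matters. Recovered depth ran from 16403903 to 49026986 reads per library, with a median of 37270234. These reads carry no molecular identifiers, and depth enters the text as a total and not as an interval. Genes were matched by symbol to the GENCODE vM21 annotation of GRCm38, which shares its chromosome coordinates with mm10, and all 52 of the 52 genes looked up were found.

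The plan made before the data were examined was to test the values as they are if the table held log2 values, keeping genes at 3.5 or more in at least 4 libraries. Because the lowest value in the table lies above 3.5, that minimum removes nothing. Genes were instead kept where the normalized count, with the transform undone, was 10 or more in at least 4 libraries, which is the minimum the plan gave for values that are not logged, and 19387 genes were kept. The literal minimum is reported as an alternative. No edgeR or DESeq2 test was run here, because the table is not a count table. limma's voom on the recovered reads was run in their place.

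limma 3.58.1 (R 4.3.3, statmod 1.5.0) fitted 1 mean per group over all 29 libraries, with a mean-variance trend and robust moderation, so that the 6 groups share 1 estimate of the spread. Comparisons were contrasts of these means, and 3 calorie-restricted (CR) diets against LFD used the mean of the LFCR, MCR and ICR means. Differences among the CR diets were tested with 1 F-test per gene. P-values were adjusted with the Benjamini-Hochberg method over genes, with a threshold of 0.05. Every adjusted p printed for a gene is from limma with this adjustment.

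The rule for named genes, also fixed before the data were examined, takes the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with a mean normalized count of 50 or more, up to 4 members with the smallest adjusted p from each list that passed, and the readouts Lep, Adipoq and Adgre1. Some genes that met this rule are not reported here. Genes named outside this rule, lymph node markers aside, are marked as chosen after their values were seen. Mup10 and Mup18 belong to a family of near-identical genes, as do the hemoglobin genes, and reads shared between copies make their separate values uncertain.

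Gene lists fixed before the data were examined were tested with limma's fry, which asks whether the genes of a list move, on balance, in 1 direction, with Benjamini-Hochberg adjustment over 222 tests (37 lists in 6 comparisons). The lists cover mature adipocyte, white fat expansion, thermogenic adipocyte, fatty acid synthesis, fatty acid oxidation, cholesterol synthesis, oxidative phosphorylation and citrate cycle genes. Immune lists cover macrophage, lipid-associated macrophage, cytokines and acute phase, interferon response, T and NK cell, B cell, neutrophil, mast cell and complement genes. Lists of other cells and structures cover collagen and matrix, fibroblast progenitor, luminal epithelium, basal epithelium, milk protein, skeletal muscle, endothelium, smooth muscle and pericyte, Schwann cell, keratinocyte and red blood cell genes. The remainder cover cell cycle, circadian clock, fasting and glucocorticoid, insulin and IGF signalling, endoplasmic reticulum stress, immediate early and heat shock, hypoxia and glycolysis, ribosomal protein and nuclear retained RNA genes. A list of 9 mitochondrially encoded genes had 0 members in the table and was not tested. Each list was also tested with camera, with a preset correlation of 0.01 and with the correlation estimated from the data. Of the 49 calls by fry, 49 were also made by camera with the preset correlation, in the same direction, and 0 with the estimated correlation. Camera with the preset correlation called 112 of the 222 tests in all, so its overlap with fry is weak support.

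An obesity score placed each mouse on the line from the Obese mean (0) to the Control mean (1) over the genes past the threshold between these groups, with a Control or Obese library left out of its own group mean when it was scored. The genes were chosen with all Control and Obese libraries, so the scores of these 2 groups are in part set by that choice. Diets were compared with two-sided exact permutation tests. The share of the obesity change undone was the covariance of diet minus Obese with Control minus Obese, over the covariance of the obesity change with itself, with both the Obese and the Control libraries split so that each part used different ones.

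Before use, each step was tested on data simulated from each gene's real mean and spread. Genes shared no variation, so real error rates may be higher. For Obese against Control, 65% of 2-fold and 87% of 4-fold changed genes were recovered with 3 false calls among 19327 genes. For MCR against Obese the shares were 54% and 81% with 10 false calls among 19328, and for the 3 CR diets against LFD 61% and 92% with 4 among 19323. Over 20 draws without change, 5.81% of the lists had an unadjusted fry p under 0.05. With 1 changed list of the 37, that list and 2 unchanged lists were called. A simulated group with all of the obesity change undone scored 0.981 and an unchanged group 0.018.

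Alternatives were other filters, quantile normalization, recomputed size factors, only the groups compared, array quality weights, the mean of the B cell, skeletal muscle or luminal epithelium list as a covariate, sequencing lane as a term, voom, log2(normalized count + 1), and each library left out in turn (for genes and their counts, each of the groups compared). The lane, voom, log2(normalized count + 1) and literal-minimum alternatives, those without 8 libraries described in the results, and the directions within lanes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.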

Results

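Gene expression was measured in normal mammary fat of C57BL/6N mice that were lean, obese, or obese and then moved to 1 of 4 weight-loss diets. Control mice (5 libraries) received a control diet. The others became obese on a diet with 60% fat, and either remained obese (Obese, 5 libraries) or lost weight on a low-fat diet without restriction (LFD, 5), a low-fat diet with 30% calorie restriction (LFCR, 5), a Mediterranean-style diet with 30% restriction (MCR, 4) or intermittent restriction (ICR, 5). E0771 cells, a mouse line of triple-negative mammary cancer, were injected in week 25 into gland 4, and the tissue sequenced was gland 9 of the other side. The titles begin with "tumor" and the labels carry the cell line's name, whereas the tissue field, source name and design text name normal tissue. Adipoq, the adipocyte hormone adiponectin, ran from 31874 ± 11919 normalized counts in Control to 73102 ± 24398 in LFCR (SD, n = 5 each). Values were variance-stabilised log2 values, from which 16403903 to 49026986 reads per library were recovered. All 5 libraries of lane 4 lay between 16403903 and 18212783 reads, and those of the other 5 lanes at 29008340 or more. Each title carries its own number and the libraries were taken as 1 per mouse, so p-values measure the spread between these libraries. No pair within a group agreed within sampling noise (Pearson r over genes from 0.926 to 0.993).

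Libraries differed most in lymphoid transcripts. The mean of 13 B cell genes lay between 6.11 and 7.13 (log2) in 8 libraries and between 10.6 and 13.2 in the other 21, with none between. The 8 were Obese 1 and 5, LFD 1, LFCR 1 and 3, and MCR 1, 3 and 4, and they lay apart from the other 21 on the first principal component, which held 50.8% of the variance. The mammary fat pad contains a lymph node, in which B and T cells are the main cells. The B cell list had a mean of 12.5 ± 0.504 in Control, 10.2 ± 3.30 in Obese, 10.7 ± 2.60 in LFD, 9.66 ± 2.53 in LFCR, 8.05 ± 3.09 in MCR and 11.5 ± 0.619 in ICR. Counts of genes are given below under each alternative that moved them by over 1.5 times. The value of 9 that separates the 8 was set after the values were seen.

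**Figure D1:**
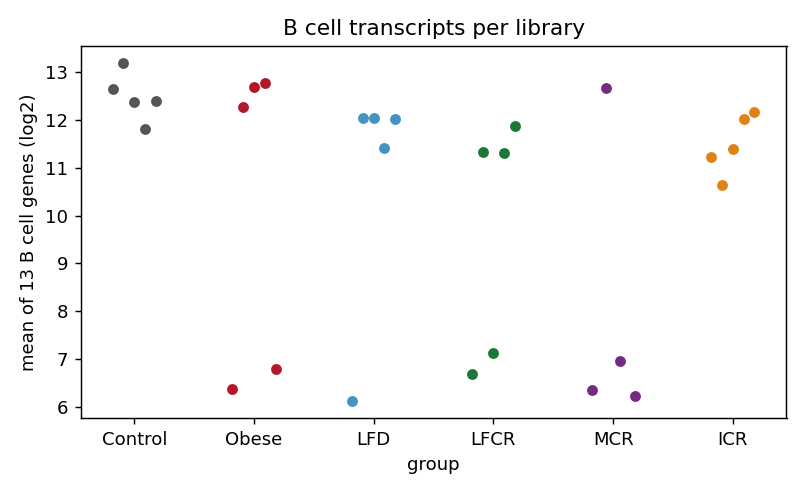
Mean of 13 B cell genes (vertical axis, log2) in each of the 29 libraries (points) by group (horizontal axis). The 8 low libraries lie at 7.13 or less, and Control and ICR hold none of them.

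The first comparison asks what obesity changed. Mest, an imprinted gene that marks fat expansion, rose from 1036 ± 921 normalized counts in Control to 25785 ± 7368 in Obese (n = 5 each; log2 difference 4.99 ± 0.69 SE, adjusted p = 8.12e-05, limma). Lep, the adipocyte hormone leptin, rose from 11678 ± 6576 to 104460 ± 39427 (3.31 ± 0.53, adjusted p = 0.000334). Itgad, an integrin subunit of tissue macrophages, rose from 50.6 ± 40.6 to 1987 ± 1304 (4.52 ± 0.51, adjusted p = 1.22e-05). Fasn, the fatty acid synthase, fell from 218110 ± 216340 to 10057 ± 4666 (-3.61 ± 0.81, adjusted p = 0.00508), and Cyp2e1, a cytochrome P450, fell from 15033 ± 12694 to 907 ± 582 (-3.99 ± 0.55, adjusted p = 7.94e-05).

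In GRCm38, Mest lies on chromosome 6 from 30723547 to 30748465, Lep on chromosome 6 from 29060220 to 29073877, and Itgad on chromosome 7 from 128154376 to 128223816. Fasn lies on chromosome 11 from 120805846 to 120824547 and Cyp2e1 on chromosome 7 from 140763739 to 140774987, and all 5 are annotated as protein-coding. Other genes among those with the largest rises were Sfrp5, a secreted Wnt regulator (4.90), the imprinted Peg10 (4.04), the kinase Cdkl4 (3.44), Mmp12, the macrophage elastase (3.37), Unc79, a sodium leak channel subunit (3.31), and Tph2, a tryptophan hydroxylase (3.14). The other largest falls were in the urinary proteins Mup10 (-4.08) and Mup18 (-3.84), the elongase Elovl6 (-3.19), the fructose transporter Slc2a5 (-3.01), the lipogenic regulator Thrsp (-2.96), the acetyl-CoA carboxylase Acaca (-2.76), the epidermal growth factor receptor ligand Areg (-2.69) and Nrxn3, a neurexin (-2.67). Adgre1, the macrophage antigen F4/80, rose from 1032 ± 327 to 2020 ± 713 counts (adjusted p = 0.0265). For Adipoq the log2 difference was 0.70 ± 0.28 (adjusted p = 0.0988).

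The calls of Mup10 and Mup18 were lost without Obese 1 (adjusted p = 0.0517 and 0.0541). Elovl6 lost its call without Control 4, Control 5 or Obese 1 (up to 0.0832), and Slc2a5 without Control 4 or 5 or Obese 1, 2, 3 or 5 (up to 0.118). Areg lost it without Control 1, 2 or 3 or Obese 1, 2 or 5 (up to 0.116). Nrxn3 lost it without any of 8 of the 10 libraries (all but Control 2 and Obese 4, up to 0.119), and Adgre1 without Control 1 or 5 or Obese 1, 2 or 5 (up to 0.0981). With the luminal covariate, the calls of Fasn (0.0530), Thrsp, Acaca, Mup10, Elovl6, Mup18, Adgre1, Slc2a5, Cldn7, Areg and Nrxn3 (0.816) were lost, at differences of -3.46 ± 1.03 for Fasn and -0.33 ± 0.83 for Nrxn3. Of the genes named for this comparison, the other alternatives ended calls among these alone. Lane as a term ended those of Slc2a5, Adgre1, Areg and Nrxn3 (up to 0.105). A fit of only these groups or voom ended some of these calls (up to 0.106 and 0.151), and the fit without the 8 libraries those of Mup18, Mup10 (at -4.18), Elovl6, Slc2a5, Nrxn3, Areg and Adgre1 (at 0.61; up to 0.270).

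Of 10 white fat expansion genes, 9 rose over all genes and 10 adjusted over the list alone (fry, Benjamini-Hochberg adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation). Of 14 lipid-associated macrophage genes, 7 rose and 9 adjusted over the list alone (adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation), among them the lipid receptor Trem2 (2.72), the galectin Lgals3 (1.43) and Atp6v0d2, a proton pump subunit (2.80). All 5 red blood cell genes rose, and 5 adjusted over the list alone (adjusted p = 0.000628; adjusted p = 0.433 with estimated correlation), including the hemoglobin gene Hbb-bs (1.83) and the heme synthesis gene Alas2 (1.69). Of 11 endothelium genes, 7 rose, such as Tie1 (0.69) and Cdh5 (0.90), the cadherin of blood vessel cells, and 9 adjusted over the list alone (adjusted p = 0.00267; adjusted p = 0.433 with estimated correlation). Of 18 luminal epithelium genes, 6 fell, including the tight junction gene Cldn7 (-0.91), and 15 adjusted over the list alone (adjusted p = 0.0200; adjusted p = 0.569 with estimated correlation). The call was lost without Obese 2 (adjusted p = 0.0531). Of 26 fatty acid synthesis genes, 6 fell and 1 rose, and 8 and 1 did so adjusted over the list alone, and the list did not pass (adjusted p = 0.209; adjusted p = 0.725 with estimated correlation). The luminal list had a mean of 10.8 ± 0.524 in Control and 9.87 ± 0.287 in Obese (SD, n = 5 each), and the skeletal muscle list 5.87 ± 0.0909 and 7.11 ± 2.22, with Obese 2 at 11.1.

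In all, 1830 genes were higher and 666 lower in Obese among 19387 tested. The total of 2496 was 1357 without Control 1, 1534 without Control 5, 1090 without Obese 1, 1184 without Obese 5, 839 with the luminal epithelium covariate, 1082 in a fit of only these groups, and 628 without the 8 libraries, of which 614 were among the 2496. Lanes hold at most 1 library of a group, so no test was made within a lane. In the 4 lanes with both groups, 82.8 to 99.7% of the 2496 genes, which were called on the same libraries, differed in the pooled direction.

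The plain low-fat diet was then set against remaining obese. Cyp2e1 rose from 907 ± 582 normalized counts in Obese to 21208 ± 12458 in LFD (n = 5 each; 4.57 ± 0.55, adjusted p = 6.11e-05, limma), and Fasn from 10057 ± 4666 to 178300 ± 144800 (3.66 ± 0.81, adjusted p = 0.00911). Adrb3, the adrenergic receptor of fat cells, rose from 1607 ± 1028 to 8854 ± 3280 (2.60 ± 0.35, adjusted p = 0.000221). Itgad fell from 1987 ± 1304 to 54.3 ± 15.3 (-4.26 ± 0.51, adjusted p = 6.11e-05), Mmp12 from 2170 ± 1045 to 216 ± 211 (-3.31 ± 0.47, adjusted p = 0.000299) and Lep from 104460 ± 39427 to 17856 ± 14977 (-2.86 ± 0.53, adjusted p = 0.00256).

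The other largest rises were in Mup10 (3.70), Mup18 (3.44), Dmbt1, a secreted glycoprotein of epithelia (3.20), Thrsp (3.11), Acaca (2.78), the cytochrome oxidase subunit Cox8b (2.28) and the growth factor Ptn (2.21). Mest (-3.34), Peg10 (-3.29), Sfrp5 (-3.06), the GABA receptor subunit Gabrr2 (-2.88), Atp6v0d2 (-2.78), Tph2 (-2.71) and Unc79 (-2.48) had the other largest falls. For Adipoq and Adgre1 the log2 differences were 0.12 and -0.64 (adjusted p = 0.894 and 0.173). Calls were lost for Dmbt1 without LFD 4 (adjusted p = 0.0522) and for Sfrp5 without Obese 1 or LFD 4 or 5 (up to 0.0653). Cox8b lost its call without Obese 1 or 5 or LFD 3, 4 or 5 (up to 0.0907), and Mup10 without any of 7 of the 10 libraries (all but Obese 5 and LFD 1 and 2, up to 0.144). Mup18 did so without any of 8 (all but LFD 1 and 2, up to 0.164), and Ptn without any of 7 (all but Obese 4 and 5 and LFD 2, up to 0.105). With the luminal covariate only Cyp2e1 and Itgad kept their calls among the genes named for this comparison (the others from 0.128 for Mmp12 to 0.977 for Ptn, which turned). Some of their differences stayed near those above with larger SEs, as for Fasn (3.46 ± 1.15), Mmp12 (-3.04 ± 0.66) and Lgals3 (-1.29), and others shrank, as for Dmbt1 (1.35) and Epcam (0.25). The fit of only these groups ended several calls, from Fasn (0.0522) to Mup18 (0.114), the fit without the 8 libraries those of Mest (at -3.33), Thrsp (at 3.71), Acaca, Cox8b, Sfrp5, Mup18, Mup10, Ptn and Dmbt1 (up to 0.117), and voom those of Cox8b, Mup10 and Mup18 (up to 0.190). Lane as a term ended those of Mup10 and Mup18 (0.0704 and 0.0833), and other filters, quantile normalization or the muscle covariate those of Ptn, Mup10 or Mup18 (up to 0.0805).

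Of 14 lipid-associated macrophage genes, 6 fell and 7 adjusted over the list alone (fry adjusted p = 0.000890; adjusted p = 0.433 with estimated correlation), including Trem2 (-2.33) and Lgals3 (-1.28). Of 10 white fat expansion genes, 5 fell and 6 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.433 with estimated correlation); the call was lost without the 8 libraries (adjusted p = 0.1002) and with the luminal covariate (0.215). Of 18 luminal epithelium genes, 11 rose and 17 adjusted over the list alone (adjusted p = 0.00113; adjusted p = 0.433 with estimated correlation), among them Cldn7 (1.19), the cell surface marker Epcam (1.29) and the cadherin Cdh1 (1.15). The luminal list had a mean of 11.1 ± 0.696 in LFD and 9.87 ± 0.287 in Obese, and its call was lost with its own mean as the covariate (0.897). Neither the fatty acid synthesis nor the macrophage list passed: 3 of 26 genes rose and 5 adjusted over the list alone (adjusted p = 0.166; adjusted p = 0.650 with estimated correlation), and 2 of 17 fell and 3 adjusted over the list alone (adjusted p = 0.312; adjusted p = 0.750 with estimated correlation).

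The diet raised 524 genes and lowered 635. This total of 1159 was 8 with the luminal covariate, 2508 with the B cell covariate (all 1159 among them) 171 without the 8 libraries (154 of them shared), 140 in a fit of only these groups and 3744 with array quality weights. Without Obese 1, 2, 3 or 5 it was 507, 711, 731 or 696, and without LFD 3, 4 or 5 it was 621, 456 or 623. Within 4 lanes, 91.9 to 99.6% of the 1159 had the pooled direction.

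Low-fat calorie restriction was set against remaining obese as well. Fasn reached 746520 ± 231550 normalized counts in LFCR against 10057 ± 4666 in Obese (n = 5 each; 6.29 ± 0.81, adjusted p = 1.07e-05, limma), and Cyp2e1 68020 ± 22565 against 907 ± 582 (6.46 ± 0.55, adjusted p = 1.55e-07). Acly, which makes cytosolic acetyl-CoA from citrate, rose from 5325 ± 331 to 104940 ± 46536 (4.18 ± 0.71, adjusted p = 0.000166). Itgad fell from 1987 ± 1304 to 16.7 ± 14.6 (-5.40 ± 0.51, adjusted p = 8.07e-07) and Lep from 104460 ± 39427 to 20127 ± 11429 (-2.44 ± 0.53, adjusted p = 0.00148).

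The other largest rises were in Elovl6 (6.03), Slc2a5 (5.32), Thrsp (5.32), Acaca (5.03), Mup10 (4.37), Lrtm1, a membrane protein (4.34), and the acetyl-CoA synthetase Acss2 (4.32). The other largest falls were in Sfrp5 (-4.19), Mmp12 (-3.95), Mest (-3.84), Peg10 (-3.50), Gabrr2 (-3.33), Atp6v0d2 (-3.26), the calcium channel Cacna1e (-3.25), Cdkl4 (-3.22) and Tph2 (-3.06). Adgre1 fell from 2020 ± 713 to 664 ± 226 counts (-1.53, adjusted p = 0.000246), and for Adipoq the difference was 0.54 (adjusted p = 0.181). Each of these calls held when any single Obese or LFCR library was left out.

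**Figure D2:**
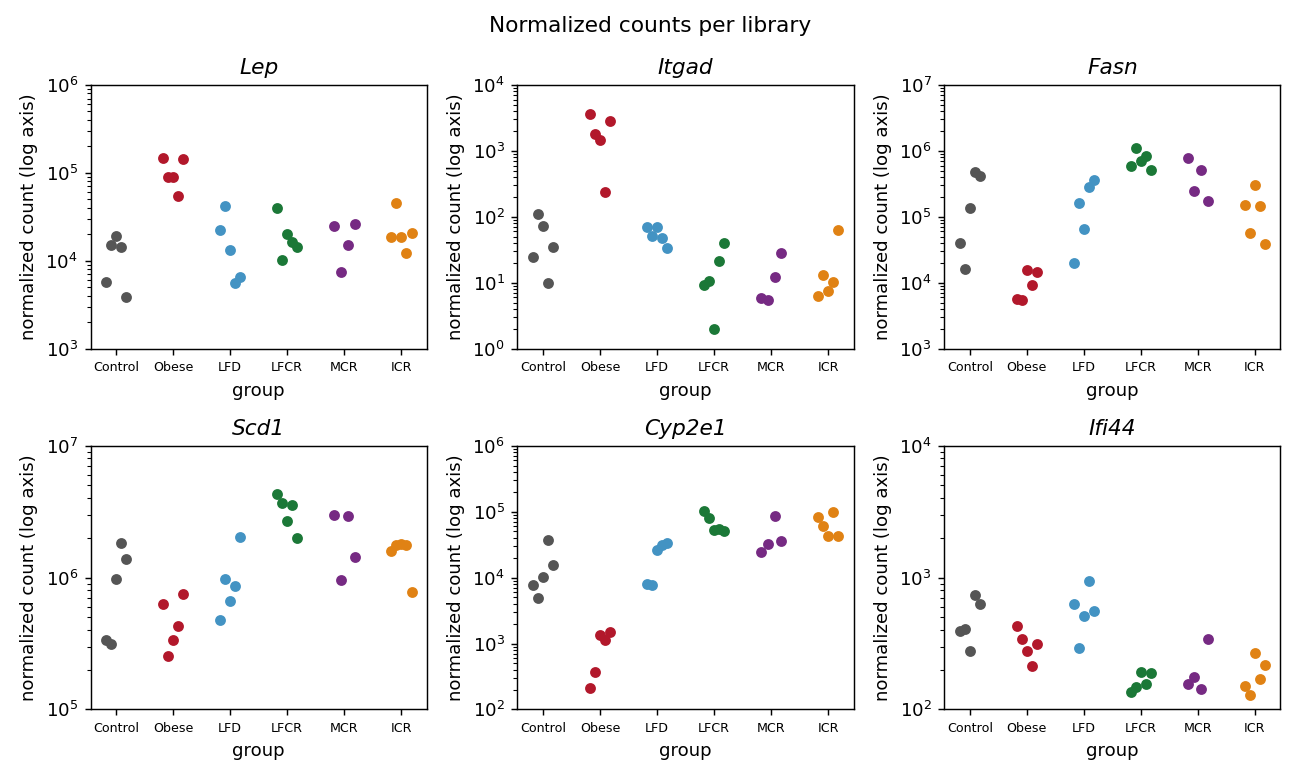
Normalized count per library (points; vertical log axis) of Lep, Itgad, Fasn, Scd1 (chosen after its values were seen), Cyp2e1 and Ifi44 by group (horizontal axis). Lep ran from 54354 to 146330 in Obese and reached at most 45062 elsewhere; Itgad was 233.8 or more in Obese and at most 110 elsewhere.

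Of 26 fatty acid synthesis genes, 23 rose in LFCR and 24 adjusted over the list alone, with a median log2 difference of 2.25 (fry adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation), and the list mean differed by 1.71 to 3.54 within 4 lanes. All 17 citrate cycle genes rose, and 17 adjusted over the list alone (adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation), such as Cs, the citrate synthase (1.54), Pdha1, a pyruvate dehydrogenase subunit (2.13), and Suclg2, a succinyl-CoA ligase subunit (1.10). Of 48 oxidative phosphorylation genes, 46 rose and 46 adjusted over the list alone (adjusted p = 0.000662; adjusted p = 0.433 with estimated correlation), including the succinate dehydrogenase subunits Sdha (1.30) and Sdhb (1.32). Of 22 mature adipocyte genes, 14 rose and 15 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.569 with estimated correlation), including Adrb3 (3.38), the adipokine gene Cfd (2.22), Slc2a4, the insulin-responsive glucose transporter (2.08), and Retn (1.99). Of 17 circadian clock genes, 9 rose, 2 fell, and 11 and 2 did so adjusted over the list alone (adjusted p = 0.00267; adjusted p = 0.502 with estimated correlation); Hlf (1.68) rose and Arntl (-1.57), which encodes BMAL1, fell.

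Of 14 lipid-associated macrophage genes, 8 fell, and 9 fell and 1 rose adjusted over the list alone (adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation). Of 17 macrophage genes, 12 fell and 13 adjusted over the list alone (adjusted p = 0.000938; adjusted p = 0.448 with estimated correlation), among them the integrin Itgam (-1.57) and the lysosomal protein gene Cd68 (-1.57). Of 22 cytokine and acute phase genes, 9 fell and 10 adjusted over the list alone (adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation), led by the interleukin 1 antagonist Il1rn (-2.90), the chemokine Ccl7 (-2.33) and serum amyloid Saa3 (-2.76). Of 12 immediate early and heat shock genes, which also respond to tissue handling, 6 fell, as in Atf3 (-1.70), and 7 adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.569 with estimated correlation).

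Further lists passed. Of 20 interferon response genes, 12 fell and 13 adjusted over the list alone (adjusted p = 0.0216; adjusted p = 0.599 with estimated correlation), lost without Obese 1 (0.0557). Of 27 collagen and matrix genes, 9 fell, as in Sparc (-1.52), and 15 adjusted over the list alone (adjusted p = 0.0301; adjusted p = 0.639 with estimated correlation), lost without Obese 1 or 5 or LFCR 2 or 4 (up to 0.0849). Of 10 complement genes, 4 fell and 4 adjusted over the list alone (adjusted p = 0.0359; adjusted p = 0.642 with estimated correlation), lost without Obese 2 or 5 or LFCR 2, 3 or 4 (up to 0.0876). Of 10 neutrophil genes, 4 fell and 4 adjusted over the list alone (adjusted p = 0.0359; adjusted p = 0.642 with estimated correlation), lost without Obese 2, 3 or 4 or LFCR 1, 2 or 3 (up to 0.106). Of 22 cell cycle genes, 10 fell and 15 adjusted over the list alone (adjusted p = 0.0467; adjusted p = 0.642 with estimated correlation). Of 10 white fat expansion genes, 5 fell and 5 adjusted over the list alone (adjusted p = 0.0479; adjusted p = 0.654 with estimated correlation). The last 2 calls were lost in 13 and 15 of the 29 leave-outs. For cell cycle these were without Obese 2 to 5, LFCR 1 to 3, ICR 1 to 4, LFD 3 or Control 5 (up to 0.112). For white fat expansion they were without any Obese library but 4, any LFCR library but 1, ICR 1, 3, 4 or 5, LFD 3 or MCR 1 or 3 (up to 0.120). Without the 8 libraries the interferon, collagen, complement, cell cycle, circadian clock, immediate early and white fat expansion calls were lost (adjusted p = 0.285, 0.0766, 0.128, 0.149, 0.105, 0.0989 and 0.123). The white fat expansion, neutrophil, cell cycle and complement calls were also lost with the muscle or the luminal covariate (0.0501 to 0.0792), and with lane as a term those of white fat expansion and complement (0.0995 and 0.0716).

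LFCR raised 2316 genes and lowered 1826 against Obese, and no left-out library of these groups moved this total of 4142 by over 1.5 times. With the B cell covariate it was 5999, with all 4142 among them, with array quality weights 7716, and without the 8 libraries it was 3600, of which 2765 were shared. Within 4 lanes, 88.8 to 99.9% of the 4142 had the pooled direction.

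In MCR, 3 of the 4 libraries were among the 8 with few B cell transcripts, as were 2 of the 5 Obese libraries. Cyp2e1 rose from 907 ± 582 normalized counts in Obese to 44153 ± 27301 in MCR (n = 5 and 4; 5.73 ± 0.58, adjusted p = 3.43e-06, limma) and Fasn from 10057 ± 4666 to 431510 ± 279850 (5.31 ± 0.86, adjusted p = 0.000309). Itgad fell from 1987 ± 1304 to 13.0 ± 10.5 (-5.51 ± 0.54, adjusted p = 3.43e-06) and Lep from 104460 ± 39427 to 18281 ± 8751 (-2.58 ± 0.56, adjusted p = 0.00361). Adgre1 fell by 1.36 on the log2 scale (adjusted p = 0.00309), and for Adipoq the difference was 0.35 (adjusted p = 0.473).

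The other largest rises were in Mup10 (4.85), Elovl6 (4.61), Mup18 (4.47), Thrsp (4.41), Acaca (4.27), Slc2a5 (4.14), Acss2 (3.48) and Cyp2f2, a cytochrome P450 (3.42). The other largest falls were in Sfrp5 (-4.38), Mest (-4.24), Mmp12 (-3.92), Cacna1e (-3.29), Gabrr2 (-3.25), Atp6v0d2 (-3.16), Cdkl4 (-3.13) and Peg10 (-3.10). Of these, Mup18 lost its call without MCR 3 (adjusted p = 0.0549), and voom ended those of Slc2a5 and Mup18 (0.0641 and 0.0660). Without the 8 libraries, Cyp2e1, Itgad, Cyp2f2, Mmp12, Cdkl4, Saa3 and Cdkn1a kept their calls and the other genes said to rise or fall in this comparison lost them (from 0.0625 for Fos to 0.435 for Slc2a5), some at differences no smaller than above, as for Sfrp5 (-5.13 ± 1.22), Mest (-4.80), Lep (-3.35) and Mup10 (5.15), and others at smaller ones, as for Pnpla3 (1.96) and Cacna1e (-1.95). A fit of only these groups ended those of Atf3, Peg10, Saa3 and Fos (up to 0.0847).

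Of 26 fatty acid synthesis genes, 18 rose in MCR and 22 adjusted over the list alone (fry adjusted p = 0.00553; adjusted p = 0.444 with estimated correlation), among them the lipid droplet gene Pnpla3 (3.01). Of 48 oxidative phosphorylation genes, 43 rose and 45 adjusted over the list alone (adjusted p = 0.00331; adjusted p = 0.433 with estimated correlation). Of 17 citrate cycle genes, 14 rose and 16 adjusted over the list alone (adjusted p = 0.00316; adjusted p = 0.433 with estimated correlation), such as Cs (1.32) and Suclg2 (0.96). Of 14 lipid-associated macrophage genes, 8 fell and 8 adjusted over the list alone (adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation). Of 17 macrophage genes, 9 fell and 12 adjusted over the list alone (adjusted p = 0.00331; adjusted p = 0.444 with estimated correlation). Of 22 cytokine and acute phase genes, 5 fell and 6 adjusted over the list alone (adjusted p = 0.00742; adjusted p = 0.540 with estimated correlation), such as Il1rn (-2.71) and Saa3 (-2.83). Without the 8 libraries the lipid-associated macrophage call held and the fatty acid synthesis, oxidative phosphorylation, citrate cycle, macrophage and cytokine calls were lost (adjusted p = 0.331, 0.285, 0.331, 0.124 and 0.239), with 1 MCR library left and assumed to vary like the other groups.

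Other lists passed in MCR too. Of 12 immediate early and heat shock genes, 2 fell, Fos (-1.75) and Atf3 (-1.71), and 5 adjusted over the list alone (adjusted p = 0.0245; adjusted p = 0.569 with estimated correlation), lost without Obese 1 or MCR 3 (up to 0.0822). Of 14 fasting and glucocorticoid genes, 6 fell, such as the cell cycle inhibitor Cdkn1a (-1.21), and 9 adjusted over the list alone (adjusted p = 0.0359; adjusted p = 0.599 with estimated correlation), lost without Obese 1 or 5 or MCR 1 or 2 (up to 0.0921). Of 23 cholesterol synthesis genes, 6 rose, such as Tm7sf2 (1.09), and 11 rose and 1 fell adjusted over the list alone (adjusted p = 0.0359; adjusted p = 0.569 with estimated correlation), lost without Obese 2, 3 or 4 or MCR 1, 3 or 4 (up to 0.139). Of 10 complement genes, 4 fell and 4 adjusted over the list alone (adjusted p = 0.0399; adjusted p = 0.616 with estimated correlation), lost without Obese 2 or 5, MCR 1, 2 or 4 or ICR 1 (up to 0.0921). Of 17 circadian clock genes, 3 rose and 3 adjusted over the list alone (adjusted p = 0.0458; adjusted p = 0.569 with estimated correlation). This call was lost in 14 of 29 leave-outs, without any Obese library but 4, any MCR library but 2, ICR 1, 3 or 4, LFD 1 or 3 or LFCR 2 or 4 (up to 0.142). Of 10 white fat expansion genes, 5 fell and 5 adjusted over the list alone (adjusted p = 0.0467; adjusted p = 0.642 with estimated correlation). It was lost in 13 of 29, without any Obese library but 4, MCR 1, 2 or 3, ICR 1, 3 or 4, LFD 3 or LFCR 3 or 4 (up to 0.161). Without the 8 libraries these 6 calls were lost too, in the order given (adjusted p = 0.419, 0.111, 0.674, 0.224, 0.640 and 0.0865). The cholesterol, complement, clock and white fat expansion calls were also lost with the muscle covariate, the luminal covariate or lane as a term, and the fasting call with the latter 2 (0.0501 to 0.108 in all), and the B cell covariate ended the cholesterol and clock calls (0.0648 and 0.0917).

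MCR raised 1292 genes and lowered 1103 against Obese, and after quantile normalization 1615 and 813, so that the share higher moved from 53.9% to 66.5%. The total of 2395 was 101 without the 8 libraries (78 shared), 1590 with lane as a term, 1135 in a fit of only these groups, 9860 with array quality weights, and 1563, 1202, 4507 or 1279 without Obese 2, MCR 1, MCR 2 or MCR 3. Within 3 lanes, 96.2 to 99.7% of the 2395 had the pooled direction.

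Intermittent restriction was also set against remaining obese. Cyp2e1 rose from 907 ± 582 normalized counts in Obese to 65440 ± 25194 in ICR (n = 5 each; 6.38 ± 0.55, adjusted p = 2.05e-07, limma), and Cyp2f2 from 211 ± 108 to 3693 ± 1406 (4.00 ± 0.42, adjusted p = 2.61e-06). Alb, which encodes the plasma protein albumin, rose from 359.7 ± 159.7 to 2863 ± 783 (2.97 ± 0.40, adjusted p = 4.34e-05). Mmp12 fell from 2170 ± 1045 to 91.7 ± 34.8 (-4.06 ± 0.47, adjusted p = 8.63e-06), Itgad from 1987 ± 1304 to 20.1 ± 24.4 (-5.32 ± 0.51, adjusted p = 1.10e-06) and Lep from 104460 ± 39427 to 23144 ± 12659 (-2.22 ± 0.53, adjusted p = 0.00774).

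The other largest rises were in Mup10 (4.58), Mup18 (4.25), Thrsp (3.70), Fasn (3.55), Acsm3, an acyl-CoA synthetase (2.95), Adrb3 (2.72) and Acaca (2.68). The other largest falls were in Sfrp5 (-3.45), Peg10 (-3.44), Cdkl4 (-3.44), Tph2 (-3.28), the chromatin protein Hmga2 (-3.11), Atp6v0d2 (-3.08), Unc79 (-2.99) and Prkag3, a subunit of AMP-activated kinase (-2.91). Adgre1 fell by 1.13 on the log2 scale (adjusted p = 0.00857), and for Adipoq the difference was 0.25 (adjusted p = 0.647). All of the gene calls in this and the preceding paragraph held when any single Obese or ICR library was left out. Voom ended the calls of Mup10 and Mup18 (0.0676 and 0.0898), and the fit without the 8 libraries that of Adgre1 (0.0602).

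Of 14 lipid-associated macrophage genes, 7 fell in ICR and 7 adjusted over the list alone (fry adjusted p = 0.000288; adjusted p = 0.433 with estimated correlation), such as Trem2 (-2.51) and Lgals3 (-1.60). Of 22 cytokine and acute phase genes, 8 fell and 10 adjusted over the list alone (adjusted p = 0.00276; adjusted p = 0.433 with estimated correlation), including Il1rn (-2.66) and Ccl7 (-2.07). Of 9 Schwann cell genes, 3 rose, such as Cdh19 (1.56), and 8 adjusted over the list alone (adjusted p = 0.0234; adjusted p = 0.542 with estimated correlation), lost without ICR 1, Obese 2 or Obese 3 (up to 0.0634). Of 17 circadian clock genes, 6 rose and 2 fell, and 9 and 2 did so adjusted over the list alone (adjusted p = 0.0301; adjusted p = 0.569 with estimated correlation), lost without ICR 1 or 2 or Obese 2 or 3 (up to 0.0619). Of 20 interferon response genes, 3 fell, including Bst2 (-0.94) and Xaf1 (-0.54), and 11 adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.569 with estimated correlation), lost without ICR 1, 2 or 4 or any Obese library but 4 (up to 0.0946). Xaf1 itself lost its call without ICR 1, ICR 2 or Obese 1 (up to 0.0771) and without the 8 libraries (0.106). Of 11 endothelium genes, 5 fell, such as Pecam1 (-0.56), and 7 adjusted over the list alone (adjusted p = 0.0480; adjusted p = 0.569 with estimated correlation). The endothelium call was kept in 11 of 29 leave-outs (Control 1 to 4, Obese 3 and 4, LFD 2 and 4, LFCR 3 and MCR 2 and 4) and at most 0.133 in the others. Without the 8 libraries the circadian clock, interferon and endothelium calls were lost (adjusted p = 0.128, 0.239 and 0.134). The muscle covariate ended them too (0.0501 each), the luminal covariate ended the Schwann cell and clock calls (0.0770 and 0.105), and lane as a term and quantile normalization the endothelium call (0.114 and 0.0761).

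ICR raised 773 genes and lowered 1013, 1786 in all. With the B cell covariate the total was 3995, with all 1786 among them, with array quality weights 4500, and no left-out library of these groups moved it by over 1.5 times. Within 4 lanes, 94.7 to 99.7% of the 1786 had the pooled direction.

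The study's title sets calorie restriction against the unrestricted low-fat diet, and the mean of LFCR, MCR and ICR was compared with LFD. Of 20 interferon response genes, 12 were lower in the CR diets, and the list's call was lost with estimated correlation (adjusted p = 0.433). Ifi44, an interferon-induced gene on chromosome 3 from 151730922 to 151749960, was at 586 ± 234 normalized counts in LFD (n = 5) and at 164 ± 24.2, 205 ± 94.5 and 188 ± 56.0 in LFCR, MCR and ICR (n = 5, 4 and 5; -1.49 ± 0.22, adjusted p = 0.00140, limma). Cyp2f2 was at 935 ± 475 in LFD and rose to 3666 ± 1222, 2357 ± 512 and 3693 ± 1406 (1.94 ± 0.35, adjusted p = 0.00627). Dmbt1 fell from 18591 ± 8626 to 1963 ± 644, 2338 ± 1369 and 2143 ± 2088 (-3.31 ± 0.63, adjusted p = 0.00808). Ucp1, the uncoupling protein of brown and beige fat, was at 1202 ± 1380 in LFD and at 31.0 ± 21.8, 19.8 ± 17.0 and 3.86 ± 3.19 in the CR diets (-3.33 ± 0.93, adjusted p = 0.0466). Its call was lost in 14 of 19 leave-outs (all but LFD 1 and 2, LFCR 4 and 5 and MCR 2, up to 0.159).

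The other largest rises were in Lrtm1 (1.76), the claudin Cldn22 (1.76), the membrane protein gene Tmem179 (1.72), Cyp2e1 (1.62), Alb (1.61), the acetoacetyl-CoA synthetase Aacs (1.43), the folate enzyme Aldh1l1 (1.25), the acyl-CoA thioesterase Acot4 (1.24) and the muscle gene Myom3 (1.21). The skeletal muscle list had a mean of 7.32 ± 1.66 in LFD and 6.60 ± 1.61, 6.33 ± 1.30 and 6.38 ± 1.05 in LFCR, MCR and ICR. The other largest falls were in Akr1cl, an aldo-keto reductase (-2.87), the fatty acid binding protein Fabp3 (-2.29), the chitinase-like Chil1 (-2.08), the dipeptidase Dpep2 (-2.05), Slfn4 (-1.83), and Prom1 (-1.63) and the keratin Krt15 (-1.61), which mark epithelial cells. For Lep, Adipoq and Adgre1 the differences were 0.45, 0.27 and -0.70 (adjusted p = 0.599, 0.550 and 0.0743). Calls were kept in every leave-out for Cyp2f2, Cldn22, Tmem179, Dmbt1, Slfn4 and Ifi44. Without LFD 1 the calls of Lrtm1, Alb, Aacs, Aldh1l1, Acot4, Myom3, Cyp2e1, Akr1cl, Chil1, Dpep2, Prom1 and Krt15 were lost (0.0627 to 0.177). Other single libraries ended calls for Lrtm1 and Acot4 (LFD 3), Akr1cl, Krt15 and Prom1 (LFD 4), Chil1 and Dpep2 (LFD 3 or 4) and Fabp3 (LFD 4 or 5, up to 0.0784). The same was true for Aacs (LFD 3, LFCR 2, MCR 1 or MCR 3), Aldh1l1 (LFD 3, LFD 4, MCR 1 or MCR 3), Myom3 (LFD 3, 4 or 5, MCR 1 or 3 or ICR 2, up to 0.142) and Cyp2e1 (all but LFD 5, LFCR 5, MCR 2, ICR 3 and ICR 5). No gene named as higher or lower in this comparison kept its call with the luminal covariate (0.212 to 0.447) or without the 8 libraries (0.0710 to 0.610). Without the 8, Ucp1 (-4.07 ± 1.10), Slfn4 (-1.92) and Ifi44 (-1.48) differed by about as much or more, and Alb (1.00) and Akr1cl (-1.66) by less. With the covariate the differences of Lrtm1 (1.76), Tmem179 (1.73), Cyp2e1 (1.94) and Alb (1.68) were no smaller, and those of Prom1 (-0.51) and Dpep2 (-0.87) shrank. The muscle covariate and lane as a term ended those of Aldh1l1, Aacs, Myom3, Cyp2e1 and Ucp1 (up to 0.0769 and 0.0885), voom those of Cyp2e1 and Ucp1 (0.0718 and 0.182), and other filters, quantile normalization, log2(normalized count + 1) or a fit of only these groups those of Aacs, Myom3, Cyp2e1 or Ucp1 (up to 0.0750).

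Of 20 interferon response genes, 12 fell in the CR diets and 17 adjusted over the list alone, with a median of -0.75 (fry adjusted p = 0.000862; adjusted p = 0.433 with estimated correlation). Among them were the antiviral oligoadenylate synthetase genes Oas2 (-1.27), Oas1a (-1.17) and Oasl2 (-1.13). The list mean was lower in the CR diets within each of 5 lanes (-1.18 to -0.52). Of 18 luminal epithelium genes, 4 fell and 13 adjusted over the list alone (adjusted p = 0.00793; adjusted p = 0.433 with estimated correlation). Of 10 basal epithelium genes, 3 fell, such as Lgals7 (-1.39), and 5 adjusted over the list alone (adjusted p = 0.0108; adjusted p = 0.433 with estimated correlation). The luminal list had a mean of 11.1 ± 0.696 in LFD and 10.1 ± 0.317, 10.4 ± 0.115 and 10.4 ± 0.241 in LFCR, MCR and ICR. Both epithelial calls were lost without the 8 libraries (adjusted p = 0.149 each) and with the luminal covariate (0.939 for luminal, which turned, and 0.708 for basal), and the interferon call held in both fits.

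Of 23 cholesterol synthesis genes, 4 rose and 9 adjusted over the list alone (adjusted p = 0.0268; adjusted p = 0.470 with estimated correlation), lost without LFD 1 or 3 (up to 0.0800). Of 22 cytokine and acute phase genes, 1 fell and 3 adjusted over the list alone (adjusted p = 0.0301; adjusted p = 0.483 with estimated correlation), lost without LFD 3 (0.0800). Of 17 macrophage genes, 1 fell and 8 adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.551 with estimated correlation), lost without LFD 1, 3 or 4, LFCR 2, MCR 1, ICR 1 or Obese 2 (up to 0.0795). Of 17 citrate cycle genes, 2 rose and 15 adjusted over the list alone (adjusted p = 0.0467; adjusted p = 0.569 with estimated correlation). The citrate cycle call was kept in 11 of 29 leave-outs (the 5 Control libraries, Obese 4, LFD 4 and 5, LFCR 5, MCR 2 and ICR 5) and at most 0.123 in the others. Of 17 circadian clock genes, 3 rose, and 9 rose and 1 fell adjusted over the list alone (adjusted p = 0.0480; adjusted p = 0.569 with estimated correlation). The clock call was kept in 9 of 29 (Control 1, 2 and 4, Obese 4, LFD 4, LFCR 5, MCR 2 and 4, and ICR 5) and at most 0.107 in the others. Without the 8 libraries all 5 of these calls were lost (adjusted p = 0.285, 0.129, 0.149, 0.609 and 0.417). The muscle covariate and lane as a term each ended all 5 as well (0.0501 to 0.114), the luminal covariate those of cholesterol synthesis, citrate cycle and cytokines (up to 0.103), the B cell covariate those of citrate cycle and clock (0.0548 and 0.0793), and quantile normalization those of cytokines, citrate cycle and clock (up to 0.0794).

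In this comparison 325 genes were higher and 320 lower, and after quantile normalization 361 and 236, so that the share higher moved from 50.4% to 60.5%. The total of 645 was 1446 with the B cell covariate (all 645 among them), 316 with the muscle covariate, 3 with the luminal covariate, 284 with lane as a term, 417 without a filter, 4292 with array quality weights, and 4 without the 8 libraries. Leaving out LFD 1, 2, 3 or 4 gave 100, 1102, 139 or 165 genes, LFCR 2 gave 404, MCR 1, 2 or 3 gave 373, 1760 or 326, and ICR 2 gave 410. Within 5 lanes, 89.3 to 99.8% of the 645 had the pooled direction.

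**Figure D3:**
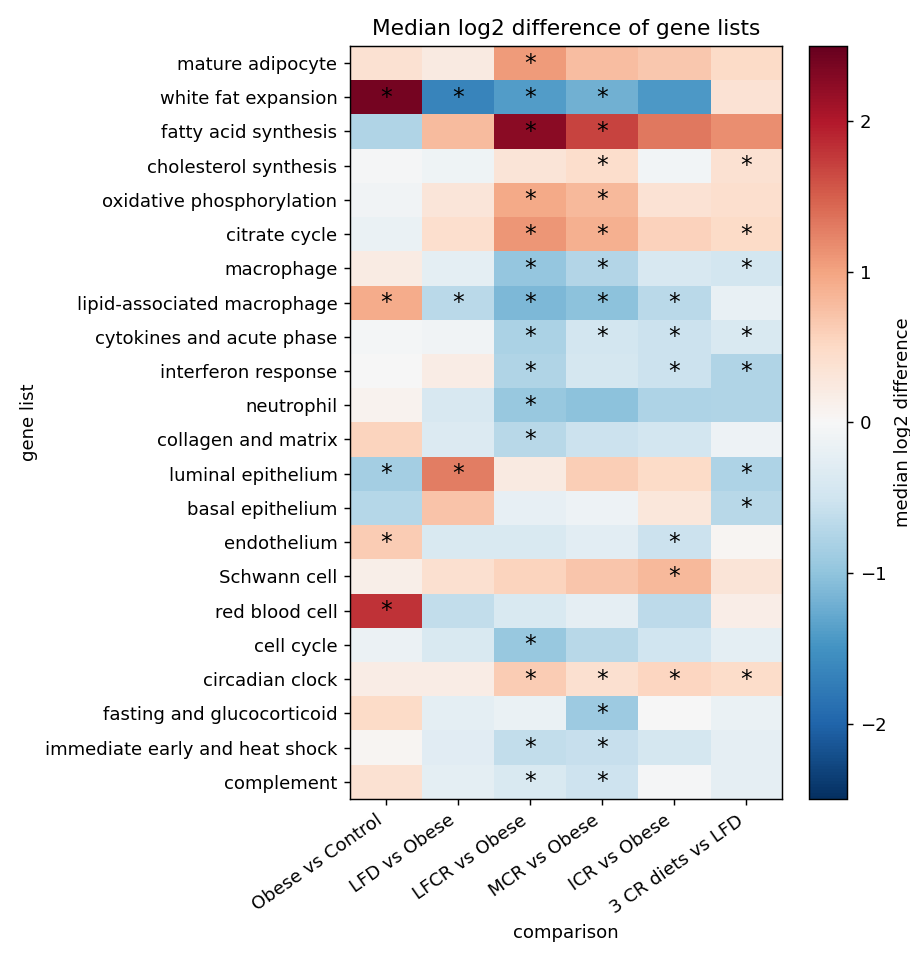
Median log2 difference (colour scale) of gene lists (vertical axis) that passed in at least 1 of 6 comparisons (horizontal axis); an asterisk marks a fry adjusted p under 0.05. Lipid-associated macrophage genes passed in 5 comparisons.

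Among the CR diets themselves, limma's F-test found 0 genes (2506 at an unadjusted p under 0.05), and voom also found 0. Leaving out MCR 2, the only MCR library outside the 8, gave 505 genes, and ICR 3, LFCR 1 or LFCR 3 gave 2, 2 or 1. With the B cell covariate 594 genes passed and with array quality weights 5406, and 4, 3 and 1 without a filter, after quantile normalization and with lane as a term. Pairs of diets were compared after the data were seen: LFCR differed from LFD in 1862 genes (1219 higher, 643 lower), MCR from LFD in 57 and ICR from LFD in 6, with 2879, 603 and 174 under the B cell covariate. ICR differed from MCR in 1 gene, and limma found 0 for MCR against LFCR and for ICR against LFCR (1028 and 2413 at an unadjusted p under 0.05), with 1216, 26 and 0 under that covariate.

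The diets were also set against lean Control mice. LFD differed in 0 genes by limma and 0 by voom, with 2425 at an unadjusted p under 0.05. LFCR differed in 7383 (3890 higher, 3493 lower), MCR in 5730 (2695 higher, 3035 lower; 3560 and 2486 after quantile normalization, 47.0% against 58.9% higher) and ICR in 887 (716 higher, 171 lower). With the B cell covariate these 3 totals were 4230, 126 and 2157, and without the 8 libraries 4915, 0 and 4714. The 0 came from limma with 1 MCR library, assumed to vary like the other groups (970 genes at an unadjusted p under 0.05). Array quality weights gave 10770 for MCR and 3724 for ICR, and a fit of only these groups 1 for MCR. Without Control 1, 2, 4 or 5 the ICR total was 149, 184, 1518 or 453, and without ICR 1, 2 or 4 it was 324, 155 or 324. The LFCR total was 4364, 4468, 4703 or 4716 without Control 1, Control 2, LFCR 1 or LFCR 3. The MCR total was 1750 or 1786 without Control 1 or 2, and 763, 9117, 547 or 1714 without MCR 1, 2, 3 or 4. Within lane 4, MCR 2 and Control 3 differed in the pooled direction in 40.7% of the 5730 genes, so that this comparison did not hold there, against at least 99.0% in the other 3 lanes. For LFCR and ICR the within-lane shares ran from 97.1 to 99.3% and from 84.0 to 99.8%.

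**Figure D4:**
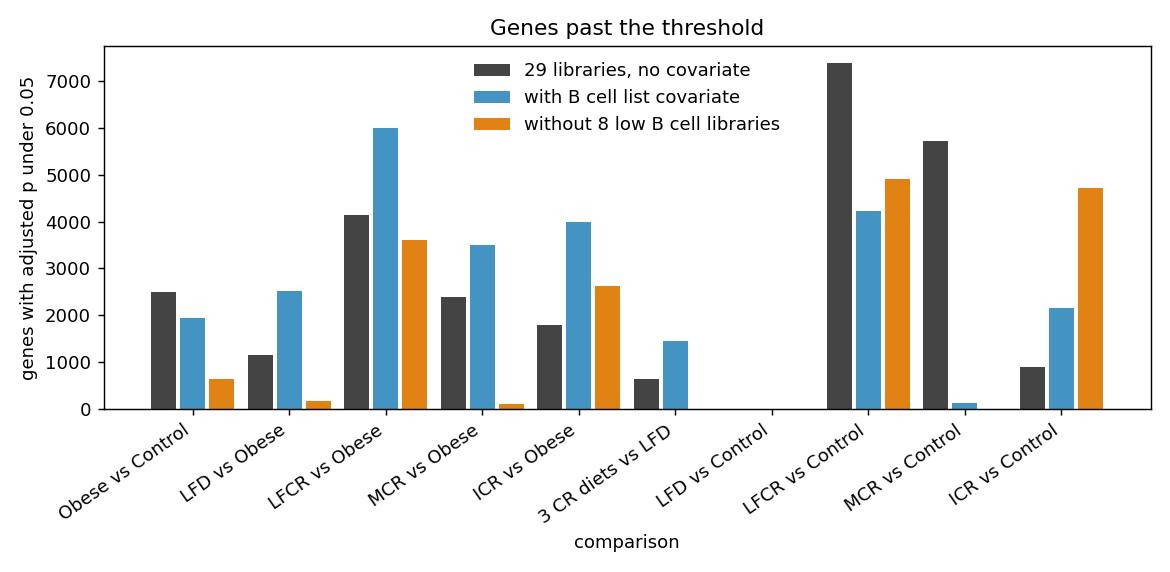
Number of genes with adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), for all 29 libraries, with the B cell list as a covariate, and without the 8 libraries with few B cell transcripts. MCR against Control fell from 5730 to 126 and 0, while LFCR against Obese had 4142, 5999 and 3600.

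How far each diet undid the obesity pattern was measured with a score per mouse over 2496 genes, in which 0 is the Obese mean and 1 the Control mean. Scores were 0.973 ± 0.178 in Control, -0.002 ± 0.381 in Obese, 0.688 ± 0.211 in LFD, 0.651 ± 0.178 in LFCR, 0.622 ± 0.273 in MCR and 0.668 ± 0.122 in ICR (SD, n = 5, and 4 for MCR). The 14 CR mice differed from the 5 LFD mice by -0.039 (two-sided exact permutation p = 0.694, adjusted 0.881), and 1 CR mouse lay above all LFD mice. LFCR, MCR and ICR alone differed from LFD by -0.037, -0.065 and -0.019 (exact permutation p = 0.746, 0.706 and 0.881, adjusted 0.881 each over 4 tests).

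**Figure D5:**
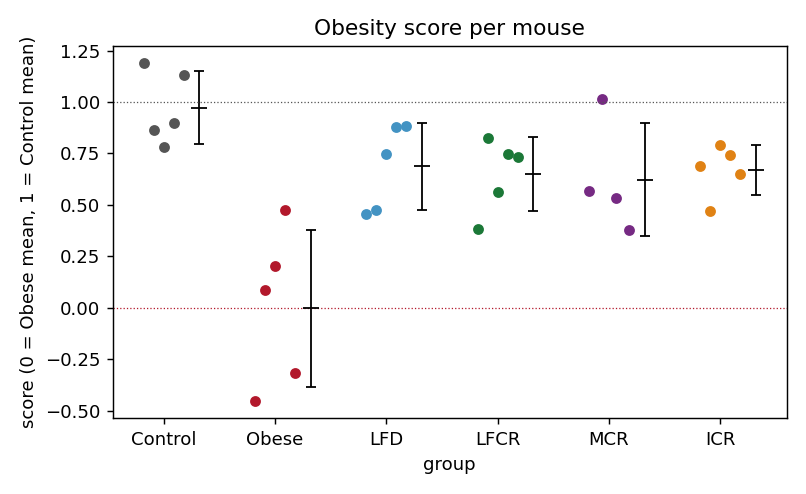
Obesity score (vertical axis, 0 is the Obese mean and 1 the Control mean) of each mouse (points) by group (horizontal axis), with the mean and SD as bars. The 4 diets had means between 0.622 and 0.688, above the Obese mean of -0.002.

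Over all tested genes, the share of the obesity change undone was 43.9 ± 46.0% in LFD, 10.8 ± 59.8% in LFCR, -9.03 ± 82.9% in MCR and 48.1 ± 22.2% in ICR (SD over mice, n = 5, 5, 4 and 5). With the Obese libraries not split, which adds covariance, the shares were 68.3, 35.2, 15.3 and 72.5%, so that the sign of MCR turned. Differences between diets were not tested. With the B cell trend removed from all values the shares were 94.9 ± 29.8%, 90.5 ± 11.1%, 92.1 ± 15.7% and 84.3 ± 19.2%. The covariance of each diet's change with the opposite of the obesity change was 0.138, 0.0710, 0.0309 and 0.146 for LFD, LFCR, MCR and ICR, against 0.0347 in simulated groups without change that shared the Obese libraries. Leave-outs gave 35.6 to 63.6% for LFD, -0.962 (without LFCR 5) to 29.7% (without LFCR 1) for LFCR, -50.3 (without MCR 2) to 8.08% (without MCR 4) for MCR and 43.9 to 56.8% for ICR.

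Of the 1830 genes that rose with obesity, 511 fell in LFD, 681 in LFCR, 533 in MCR and 634 in ICR. Independent lists would share 59.9, 172, 104 and 95.6 genes, and simulated groups without change shared 0. That 0 rests on a mean of 0.1 genes called for obesity over 10 draws, so it does not measure what the shared Obese libraries add. With the Obese libraries split so that the comparisons shared none, the mean overlaps over 10 splits were 80.9, 239, 161 and 149, against 4.53, 47.0, 23.5 and 12.5 for independent lists. Of the 666 genes that fell with obesity, 242, 195, 139 and 145 rose in the same diets, against 18.0, 79.6, 44.4 and 26.6 for independent lists. With the Obese libraries split the means were 7.3, 45.9, 23.7 and 17.2, against 0.361, 38.8, 15.0 and 3.39. In all 4 diets against Obese, 125 genes were higher and 347 lower, and 70 and 302 of these had moved the opposite way with obesity. All 4 diets share the Obese libraries, which adds to these overlaps.

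Lists that passed in no comparison are given here where their adjusted p was lowest. Of 21 fatty acid oxidation genes, 11 rose and 1 fell in LFCR against Obese (fry adjusted p = 0.0644). The fibroblast progenitor list had a median of -0.58 in LFCR against Obese (adjusted p = 0.0504) and the hypoxia and glycolysis list 0.49 (0.162), with 7 genes up and 6 down. In ICR against Obese the milk protein list had a median of 1.23 (0.0656) and the mast cell list 0.34 (0.395). The endoplasmic reticulum stress list had -0.29 in MCR against Obese (0.0533), the thermogenic adipocyte list 0.85 in LFD against Obese (0.140) and the keratinocyte list -0.10 in the CR diets against LFD (0.0684). In Obese against Control the medians were -1.78 for T and NK cell (0.193), -2.39 for B cell (0.267), and 1.25 for skeletal muscle (0.314). They were 0.30 for smooth muscle and pericyte (0.168), 0.18 for insulin and IGF signalling (0.166), -0.33 for ribosomal protein (0.154) and -0.22 for nuclear retained RNA genes (0.442).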

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

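The tests of depth, lane and diet for the 8 libraries with few B cell transcripts were chosen after those libraries had been seen, and the test of lymph node stroma genes before its values were seen. In 455 groups of 4 or 5 libraries, 30 had a highest or lowest library far from the others, and chance flags about 1 in 20 such groups. The value given for each is the gap to the nearest library as a share of the group's range.

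B cell and T and NK cell transcripts set single libraries apart in 2 groups. LFD 1 had the lowest B cell list mean of LFD, 6.11 against 11.4 to 12.0 (0.894), and the lowest T and NK cell mean, 6.44 (0.844). MCR 2 had the highest B cell mean of MCR, 12.7 against 6.23 to 6.95 (0.888), the highest T and NK cell mean, 10.2 (0.903), and the lowest endothelium mean, 11.03 against at least 11.8 (0.945).

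Over all groups, 8 libraries had a B cell mean of at most 7.13, and the other 21 at least 10.6. Low depth as the cause is argued against by the reads, since 3 of the 8 libraries held fewer than the median library. Sequencing lane as the whole cause is argued against too, because 4 lanes held both kinds of library, although lane 6 held 4 of the 8 among its 5 libraries (permutation p = 0.0678 for as many in 1 lane), so that a part played by lane stays open. Sampled tissue with little or no lymph node is a candidate explanation: the mean of 6 stroma and vessel genes of the node, such as Ccl21a and Glycam1, lay at 5.49 to 6.35 in the 8 and at 9.22 to 11.3 in the others, with 8 of 8 below all the others. Diet stays open, since the number per group gave a permutation p = 0.108.

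Other tissue lists stood apart in single libraries. The skeletal muscle mean was highest in Obese 2 (11.1 against 5.97 to 6.26, 0.942) and in ICR 4 (8.24, 0.865). The luminal epithelium mean was lowest in Control 2 (9.91 against 10.8 to 11.1, 0.711), and the milk protein mean highest in Control 1 (10.96, 0.745) and in ICR 3 (12.4, 0.878). ICR 3 also had the lowest red blood cell mean (0.956) and endoplasmic reticulum stress mean (10.7, 0.727) of ICR. The endothelium mean was highest in LFCR 3 (0.760). Lipid-associated macrophage genes were lowest in Obese 4 (10.0, 0.734) and highest in LFD 1 (10.5, 0.817).

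Fasting and glucocorticoid genes were highest in Control 4 (11.7, 0.832), Obese 1 (11.8, 0.759) and LFCR 1 (0.726). LFCR 1 also had the highest insulin and IGF signalling mean (12.3, 0.718), and Obese 1 the highest immediate early and heat shock mean (10.5, 0.801). Recovered reads were lowest in Obese 3 (0.746, on the log2 scale).

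Among single genes, Nrxn3 was lowest in Control 2 (log2 value 5.18, 0.749), Atp6v0d2 in Obese 4 (7.45, 0.816), Cyp2f2 in LFD 1 (7.64, 0.725) and Hmga2 in ICR 3 (4.16, 0.780). Gabrr2 was highest in LFCR 1 (7.44, 0.846), Itgad in ICR 5 (6.46, 0.765), Chil1 in ICR 3 (9.80, 0.712), Akr1cl in MCR 2 (7.33, 0.838) and Slfn4 in MCR 4 (8.62, 0.933).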

How the results depend on the processing

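The fits with lane as a term, voom, log2(normalized count + 1), the minimum of 3.5 taken literally, the fits without the 8 libraries with few B cell transcripts, the removal of the B cell trend and the leave-outs for the share of the obesity change undone were chosen after the data were seen, and the other alternatives before. The planned count tests and the pseudocount of 8 were not run, because the table holds log2 values. No paired analysis was possible because the animal numbers are unique to each library, and lane, which the groups share, was fitted as a term instead. Recomputed size factors lay between 1.0046 and 1.0084 and so say nothing about stability. Depth limits low genes most, and in simulated data for Obese against Control 65% of 2-fold changes were recovered. Except where a reason is given, the cause of a change was not tested.

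The number of genes past the threshold stayed within 1.5 times in all comparisons with a stricter filter (4 libraries at 50 or more), voom and log2(normalized count + 1). Without a filter and with the literal minimum of 3.5, which test more genes, the CR diets against LFD gave 417 and the F-test among the CR diets 4, and quantile normalization gave 3 for the F-test. With only the groups compared in the fit, which leaves fewer samples, Obese against Control gave 1082, LFD against Obese 140, MCR against Obese 1135 and MCR against Control 1. Array quality weights gave 3744, 7716, 9860 and 4500 for LFD, LFCR, MCR and ICR against Obese, 4292 for the CR diets against LFD, 10770 and 3724 for MCR and ICR against Control and 5406 for the F-test. The B cell covariate gave 2508 and 3995 for LFD and ICR against Obese, 1446 for the CR diets against LFD, 4230, 126 and 2157 for LFCR, MCR and ICR against Control and 594 for the F-test. The muscle covariate gave 316 for the CR diets against LFD. The luminal covariate gave 839 for Obese against Control, 8 for LFD against Obese and 3 for the CR diets against LFD, and lane gave 1590 for MCR against Obese, 284 for the CR diets against LFD and 1 for the F-test. Fits without the 8 libraries, which hold fewer samples, gave 628 for Obese against Control, 171 and 101 for LFD and MCR against Obese, 4 for the CR diets against LFD, and 4915, 0 and 4714 for LFCR, MCR and ICR against Control (limma, with 970 at an unadjusted p under 0.05 for MCR).

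Leaving out 1 library in turn gave 1090 genes (without Obese 1) to 3377 (without Obese 4) for Obese against Control, and 100 (without LFD 1) to 1760 (without MCR 2) for the CR diets against LFD. Against Obese it gave 456 (without LFD 4) to 1634 (without LFD 2) for LFD, 3215 to 4382 for LFCR, 1202 (without MCR 1) to 4507 (without MCR 2) for MCR and 1192 to 2013 for ICR. Against Control it gave 0 for LFD in every leave-out, 4364 (without Control 1) to 8157 for LFCR, 547 (without MCR 3) to 9117 (without MCR 2) for MCR and 149 (without Control 1) to 1518 (without Control 4) for ICR, and 0 to 505 (without MCR 2) for the F-test among the CR diets. The difference in obesity score from LFD ran from -0.112 to 0.034 for the CR diets, -0.112 to 0.059 for LFCR, -0.256 to 0.031 for MCR and -0.084 to 0.036 for ICR.

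The share undone was 94.9, 90.5, 92.1 and 84.3% for LFD, LFCR, MCR and ICR with the B cell trend removed, and 68.3, 35.2, 15.3 (against -9.03) and 72.5% with Obese not split.

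Directions turned with the luminal epithelium covariate for Cdh1 in Obese against Control (0.0497), for Ptn in LFD against Obese (-0.14) and for the luminal list itself in Obese against Control (adjusted p = 0.399) and in the CR diets against LFD (0.939), where the covariate removes the list's own mean. The B cell list turned in ICR against Obese without the 8 libraries, which removes the low Obese libraries (adjusted p = 0.0455). Of the 49 list calls, 45 were kept after quantile normalization, 45 with the B cell covariate, 33 with the muscle covariate, 30 with the luminal covariate, 36 with lane as a term and 20 without the 8 libraries. In every leave-out 27 were kept.

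For gene lists the value followed was the number of the 6 comparisons with a call. It was 5 for lipid-associated macrophage, 4 for white fat expansion, cytokines and acute phase and circadian clock, 3 for citrate cycle, macrophage, interferon response and luminal epithelium, 2 for fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, endothelium, immediate early and heat shock and complement, 1 for mature adipocyte, neutrophil, collagen and matrix, basal epithelium, Schwann cell, red blood cell, cell cycle and fasting and glucocorticoid, and 0 for the others. After quantile normalization it was 1 for fibroblast progenitor and endothelium and 2 for mature adipocyte. With the B cell covariate it was 1 for cholesterol synthesis, fibroblast progenitor, milk protein, smooth muscle and pericyte, keratinocyte and endoplasmic reticulum stress, 2 for mature adipocyte, neutrophil, collagen and matrix, cell cycle and circadian clock and 5 for endothelium. With the muscle covariate it was 0 for cholesterol synthesis, neutrophil, cell cycle and complement, 1 for endothelium and circadian clock and 2 for white fat expansion. With the luminal epithelium covariate it was 0 for cholesterol synthesis, luminal epithelium, Schwann cell, cell cycle, fasting and glucocorticoid and complement, 1 for white fat expansion and smooth muscle and pericyte, 2 for circadian clock and 5 for immediate early and heat shock. By camera with the preset correlation it was 1 for endoplasmic reticulum stress, 2 for B cell, skeletal muscle and fasting and glucocorticoid, 3 for fatty acid oxidation, thermogenic adipocyte, T and NK cell, basal epithelium, red blood cell and ribosomal protein, 4 for neutrophil, Schwann cell and immediate early and heat shock, 5 for mature adipocyte, oxidative phosphorylation, citrate cycle, macrophage, interferon response, luminal epithelium and cell cycle and 6 for fatty acid synthesis and collagen and matrix. With lane as a term it was 0 for cholesterol synthesis, fasting and glucocorticoid and complement, 1 for endothelium and 2 for white fat expansion and circadian clock. Once the 8 libraries were left out it was 0 for basal epithelium, cell cycle, circadian clock, fasting and glucocorticoid, immediate early and heat shock and complement, 1 for white fat expansion, fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, citrate cycle, macrophage, interferon response and B cell and 2 for mature adipocyte, cytokines and acute phase and neutrophil. By camera with the estimated correlation it was 0 for all 22 lists called in at least 1 comparison. Over the leave-outs it ran from 0 to 1 for cell cycle, endoplasmic reticulum stress, fatty acid oxidation, fibroblast progenitor, keratinocyte and milk protein, 0 to 2 for Schwann cell, fasting and glucocorticoid and neutrophil, 0 to 3 for complement, 0 to 4 for collagen and matrix, 1 to 2 for cholesterol synthesis, 1 to 3 for basal epithelium, endothelium and mature adipocyte, 1 to 4 for immediate early and heat shock and interferon response, 1 to 5 for circadian clock, 2 to 3 for luminal epithelium and oxidative phosphorylation, 2 to 4 for citrate cycle, fatty acid synthesis and macrophage, 2 to 5 for white fat expansion and 3 to 5 for cytokines and acute phase.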

Other observations

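Comparisons between single diets and the tests of the interferon and fatty acid synthesis patterns were chosen after the results were seen, and the number of other splits was planned before.

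No list test of LFCR against LFD was run, and 4 fatty acid synthesis genes are given. Against LFD, LFCR had higher Fasn (2.63 ± 0.81, limma adjusted p = 0.0396), Scd1, a desaturase named after its values were seen (1.81 ± 0.47, adjusted p = 0.0212), Acly (2.65 ± 0.71, adjusted p = 0.0241) and Elovl6 (3.40 ± 0.92, adjusted p = 0.0244). For ICR against LFD the differences were -0.10 for Fasn, 0.74 for Scd1, -0.60 for Acly and -0.14 for Elovl6 (adjusted p = 0.995, 0.757, 0.942 and 0.993). A difference between ICR and LFCR was not shown (0 genes by limma, 2413 at an unadjusted p under 0.05). The single gene that passed between ICR and MCR was Pmepa1 (1.66 ± 0.27, adjusted p = 0.027), named after its value was seen.

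Interferon response genes had a mean of 10.4 ± 0.321 in LFD, 10.3 ± 0.451 in Control and 10.2 ± 0.269 in Obese, and of 9.56 ± 0.155, 9.72 ± 0.247 and 9.65 ± 0.189 in LFCR, MCR and ICR. Lymph node content as the whole cause is argued against by an adjusted p = 0.000875 with the B cell covariate, epithelium content by 0.0370 with the luminal covariate, and lane by 0.00163 with lane as a term. The call was kept in every leave-out and lost by camera with the estimated correlation (adjusted p = 0.433). A response to calorie restriction may underlie the lower values, as a hypothesis found and tested on the same libraries. Other cell types and the time since feeding were not tested.

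Fatty acid synthesis genes rose more in LFCR against Obese than a larger share of adipocytes alone would give: the list mean rose by 2.62 and the mature adipocyte list mean by 1.13, a difference of 1.49 (two-sided exact permutation p = 0.00794 over 252 splits, the smallest they can give). Library scaling as the whole cause is argued against by the same exact permutation p = 0.00794, because a factor shared by the genes of a library cancels in this difference, apart from the transform's compression of low values, and lymph node content by an adjusted p = 0.000427 with the B cell covariate, though the list's call was lost with estimated correlation (adjusted p = 0.433). A change within adipocytes is a possible explanation and was not tested, and neither were the composition of the diet and the time since feeding.

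Other splits of the same libraries were drawn, 100 for each comparison with the real one included. No other split reached the real count for Obese against Control (2496, highest of the others 2100) or LFD against Obese (1159, 649). The same held for LFCR against Obese (4142, 2938), ICR against Obese (1786, 325), LFCR against Control (7383, 6399) and ICR against Control (887, 566). For the CR diets against LFD (645, 1929), 2 splits gave as many, so chance is not excluded. Nor is chance excluded for MCR against Obese, where 6 splits gave as many as 2395 genes and the highest gave 8334, or for MCR against Control, where 5 gave as many as 5730 and the highest 9339. The highest split put all 5 libraries with few B cell transcripts on 1 side in the former and all 3 in the latter, which points to a structure of the samples. The highest split of the CR diets against LFD, at several times the real count, also points to a structure: it put 3 such libraries among 14 on 1 side and 3 among 5 on the other. For LFD against Control and among the CR diets the real count was 0 by limma and by voom (2425 and 2506 at an unadjusted p under 0.05), all 100 splits gave as many, and the highest gave 118 and 172.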
